A study of Homo sapiens with 10 samples.

How the data were processed

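RNA from 10 libraries of stable human liver tumour lines was measured by poly(A) RNA sequencing. Per the labels, HepG2 and SK-Hep1 cells were transduced with lentivirus at a multiplicity of infection of 5 with polybrene at 10 µg/mL for 48 h. They were then selected in puromycin at 1 µg/mL for 2 weeks in medium with 10% serum, and resistant colonies were pooled. The vector carried either a tough decoy (TuD), an RNA hairpin that binds and blocks a microRNA, against the miR-17 family, or a negative control decoy (NC TuD). Each arm of each line is therefore 1 stable line. The labels do not say whether replicates were separate cultures, so the effect of the decoy cannot be told apart from differences that arose when the 2 stable lines of each cell line were made. Libraries used 150 ng of total RNA and a kit that does not record the strand, and were read as 50 bp pairs. HepG2 had 3 libraries per arm and SK-Hep1 had 2.

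The authors deposited a raw count per gene for each library and a log2 matrix of all libraries. The deposited count files hold whole numbers for 19215 gene symbols and, in the same column, totals of reads outside genes, ambiguous, not aligned uniquely or not aligned. These last entries were left out of the gene counts. They made up 11.6% to 14.1%, 0.584% to 0.619%, 4.48% to 5.04% and 2.43% to 2.87% of each column. The sources differ on how the counts were made. Per the labels of the samples, reads were aligned with STAR to hg19 and counted with HTSeq 0.5.4p5, whereas the series description names other aligners, a mouse genome and RSEM. The summary entries are of the HTSeq type and the symbols are human. In the deposited log2 matrix of 13658 genes, every value matched log2 of the count plus 0.5, divided by 1 effective library size per library. The largest departure was 1e-13. Of its genes, 42 matched the counts only after a punctuation mark in the name was changed, and 57 had no count in any library.

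Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr at its default settings by group, which left 13349 genes, and scaled by TMM. All 10 libraries entered 1 quasi-likelihood fit with 4 group means and robust dispersion estimation. The contrasts were miR-17 TuD minus NC TuD in each line, the difference between these responses, and SK-Hep1 NC TuD minus HepG2 NC TuD. A gene was called at a Benjamini-Hochberg adjusted p below 0.05, in two-sided tests over all genes tested. Errors of log2 fold changes are standard errors (SE), taken as the fold change over the root of the quasi-likelihood F. Levels are CPM with the TMM factors, as mean ± SD. On simulated counts with the dispersions of these libraries, the HepG2 comparison recovered 86%, 92%, 100% and 100% of genes changed 1.25-, 1.5-, 2- and 3-fold, with 12 false calls among 201. The SK-Hep1 comparison recovered 66%, 84%, 100% and 100%, with 11 false calls among 186. No change under 1.25-fold was simulated, so recovery below that size is not known. In the data, 1717 of 2571 calls in HepG2 and 54 of 116 in SK-Hep1 were smaller than that.

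Gene counts came to between 12884225 and 15076431 per library. At that depth 1 count is 0.0663 to 0.0776 CPM, and 3 counts, the most that a count of 0 allows, are 0.199 to 0.233 CPM. Intervals of ratios and shares are exact Poisson intervals at 95% and cover counting error only, since reads carried no molecular identifiers. Pairs of replicates differed by more than counting error, with chi-square over its degrees of freedom from 1.4 to 3.7.

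Sites for miR-17 were sought in the longest 3′ untranslated region (3′UTR) of each protein-coding gene in GENCODE 29 on GRCh38. Positions printed are on that build, while the counts were made on hg19. Of the symbols in the counts, 18183 matched directly, 729 through an older symbol and 303 not at all. A 3′UTR was available for 13248 of the 13349 tested genes, and the others were counted as not searched. An 8mer is GCACTTTA, a 7mer-m8 is GCACTTT, and a 7mer-A1 is CACTTTA, from the seed at nucleotides 2 to 8 of the mature miR-17. The main test set genes with an 8mer or 7mer-m8 against genes with none of the 3 kinds, by camera with a preset correlation of 0.01 between genes. The effect is the difference of mean log2 fold changes.

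Gene lists were tested by camera in the same way, with Benjamini-Hochberg adjustment over the 22 lists that had enough tested members, and again with the correlation estimated from the data. fry (limma 3.58.1) was run as well. The target list came from textbook and prediction knowledge of the miR-17 seed family, not from these libraries. Named genes follow a rule. For each line it takes the 8 largest changes per direction among calls with an average log2 CPM of at least 1 and arms that did not overlap. It adds up to 4 called members per list (10 from the target list) with the smallest adjusted p, and a short set named in any case, among them CDKN1A, E2F1 and BCL2L11. Of the genes the rule names, 3 are not reported here, and no others took their place. For both lines together it takes the 8 per direction with the largest smaller change, and for the difference of responses the 6 per direction with the smallest adjusted p. For the cell lines themselves it takes list members only, and the 2 most abundant of each list described were used along with ALB and AFP, a choice of examples made after the data were seen. The tests, the lists, this rule and most alternatives were chosen before the data were examined.

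Alternatives covered RLE and upper-quartile scaling, looser and stricter filters, DESeq2 1.42.0, limma-voom, non-robust fitting, each line fitted alone, a replicate block, leaving out each library in turn, and other definitions of a site. Chosen after seeing the data were the deposited log2 matrix with limma-trend, leaving out genes at least 50-fold apart between the lines, HepG2 with 2 libraries per arm, and a block with crossed replicate numbers. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.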

Results

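Poly(A) RNA was sequenced from HepG2, a liver tumour line with hepatocyte features, and SK-Hep1, another, with a reported endothelial origin. Each line carried a lentiviral decoy against the miR-17 family (miR-17 TuD) or a control decoy (NC TuD). HepG2 had 3 libraries per arm and SK-Hep1 had 2, with 12884225 to 15076431 gene counts per library. Over 8071 well-expressed genes, HepG2 libraries of 1 arm lay 0.099 to 0.137 log2 apart (root mean square) and libraries of different arms 0.16 to 0.207. In SK-Hep1 these distances were 0.125 and 0.136 within arms and 0.167 to 0.2 between them.

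The first comparison asked which transcripts differed in HepG2 when the miR-17 family was blocked. Changes are given as log2 fold change ± SE, with n = 3 per arm and adjusted p by edgeR. CPT1A, which controls entry of long-chain fatty acids into mitochondria, rose from 21.2 ± 0.991 to 59.7 ± 2.65 CPM (adjusted p = 2.72e-25). CDH1, the epithelial adhesion molecule E-cadherin, rose by 1.46 ± 0.09, from 12.6 ± 0.868 to 34.7 ± 2.0 CPM. The Schlafen family gene SLFN5 rose by 2.48 ± 0.27, and HERC5, an interferon-induced ligase for ISG15, by 2.83 ± 0.35, both from under 1 CPM. ALB (albumin) fell from 13570 ± 310 to 9499 ± 358 CPM, AFP (alpha-fetoprotein) from 7480 ± 154 to 5161 ± 241 CPM, and the fatty acid binding protein gene FABP1 from 130.7 ± 6.03 to 82.7 ± 1.95 CPM.

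Of 13349 genes tested, 2571 were called, 1425 higher and 1146 lower. Most changes were small, with a median size of 0.24 on the log2 scale, while 114 genes were at least 2-fold higher and 32 at least 2-fold lower. Among genes with an average log2 CPM of at least 1, the largest increases besides SLFN5 included ALDH8A1 (1.89 ± 0.15), FLRT3 (1.80 ± 0.19), a cell adhesion gene, the troponin gene TNNI2 (1.79 ± 0.17) and the desmosomal cadherin DSC3 (1.71 ± 0.18). They also included EFR3B (1.69 ± 0.25), the secreted IGFBP7 (1.58 ± 0.14) and the transcription factor gene KLF7 (1.57 ± 0.13). Under the same limit, the largest decreases were in PCK1, an enzyme of gluconeogenesis (-1.56 ± 0.24), the secreted phospholipase gene PLA2G2A (-1.51 ± 0.13), the mitochondrial folate enzyme gene ALDH1L2 (-1.46 ± 0.20) and STRA6, a receptor for retinol-binding protein (-1.19 ± 0.21). COL26A1 (-1.17 ± 0.09), TLE4 (-0.98 ± 0.18), ADAMTS2 (-0.98 ± 0.15) and SLC17A2 (-0.97 ± 0.17) followed. The 2 arms were different stable lines, so each of these values joins the decoy with the history of the line. On the deposited log2 matrix, a fit added after seeing the data, 20 of 110 named calls in HepG2 were lost, those of ALB, AFP, STRA6, COL26A1, ADAMTS2 and SLC17A2 among them.

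Reported or predicted targets of the miR-17 family rose as a group in HepG2. Of 69 tested members, 43 rose, 1 fell and 25 did not pass the test (47 and 2 when adjusted over the list alone). The list median was 0.21 (camera adjusted p = 3.14e-18; adjusted p = 0.0127 with an estimated correlation). ZNFX1, an RNA helicase-like gene, rose by 0.85 ± 0.05, the autophagosome transport gene FYCO1 by 0.76 ± 0.07, RGMB, a co-receptor of bone morphogenetic proteins, by 0.63 ± 0.08, and NAGK by 0.54 ± 0.07. The transforming growth factor beta receptor gene TGFBR2 rose by 0.44 ± 0.04 and CDKN1A, the cell cycle inhibitor p21, by 0.40 ± 0.04 (adjusted p = 3.6e-12). MINK1, TNFRSF21, CCND1 and SQSTM1 rose by 0.38, 0.31, 0.25 and 0.27. The cystic kidney genes PKD1 (0.26 ± 0.06) and PKD2 (0.36 ± 0.08) rose too. Other targets often named for this family did not pass: E2F1 was at 0.04 ± 0.05 (adjusted p = 0.694) and BCL2L11 at 0.06 ± 0.07. MCM7, which hosts a related microRNA cluster, was at -0.02 ± 0.04 (adjusted p = 0.781). The microRNA cluster transcript MIR17HG was not analysed here.

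Epithelial genes rose in HepG2, with 11 of 16 tested members higher and none lower, also when adjusted over the list alone. CLDN1, a tight junction gene, rose by 0.40 ± 0.04, and the keratin genes KRT19 and KRT8 by 0.24 ± 0.04 and 0.20 ± 0.03 (list camera adjusted p = 4.48e-09; adjusted p = 0.0307 with an estimated correlation). Ribosomal protein genes and MYC-bound genes fell by small amounts. The first were lower in 26 of 30 and higher in none (27 lower when adjusted over the list alone), among them RPL11 (-0.27 ± 0.03) and RPL5 (-0.21 ± 0.03). The list had adjusted p = 3.14e-18, and adjusted p = 0.0777 with an estimated correlation. Of 30 MYC-bound genes, 16 fell and none rose (17 and 1 when adjusted over the list alone), such as NPM1 (-0.26 ± 0.03) and GNL3 (-0.25 ± 0.04), with MYC itself at -0.14 ± 0.04 (adjusted p = 0.00743), a call lost without miR-17 TuD replicate 3 or NC TuD replicate 1. That list gave adjusted p = 2.34e-07, and adjusted p = 0.0777 with an estimated correlation.

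Hepatocyte genes were lower in 12 of 26 and higher in 4 (14 and 4 when adjusted over the list alone), with FGB (-0.65 ± 0.05), FGG (-0.48 ± 0.04) and FGA (-0.42 ± 0.04), which encode the fibrinogen chains, among those that fell. The list gave adjusted p = 2.22e-05, and adjusted p = 0.148 with an estimated correlation. Unfolded protein and amino acid stress genes were lower in 10 of 20 and higher in 2, the same counts as when adjusted over the list alone. HSPA5, the main chaperone of the endoplasmic reticulum, stood at -0.25 ± 0.03 and the transcription factor gene ATF4 at -0.18 ± 0.04 (list adjusted p = 0.00468; adjusted p = 0.0777 with an estimated correlation). Of 21 genes raised by TGF-beta or BMP signalling, 9 rose and 1 fell (9 and 1 adjusted over the list alone), with COL1A1 at 0.64 ± 0.11 and TGM2 at 0.27 ± 0.04, and CTGF as the member that fell (-0.22 ± 0.04). Their adjusted p was 0.00339, and adjusted p = 0.184 with an estimated correlation. Of 20 p53 targets 7 rose, such as the death receptor gene FAS (0.45 ± 0.08), and CCNG1 fell (8 and 1 adjusted over the list alone; adjusted p = 0.011, and adjusted p = 0.0777 with an estimated correlation). Of 26 interferon-stimulated genes 5 rose and none fell, also when adjusted over the list alone, OAS1 (0.68 ± 0.12) and OAS3 (0.31 ± 0.06) among them. This list gave adjusted p = 0.011, and adjusted p = 0.314 with an estimated correlation.

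Other lists did not pass by camera in HepG2, although single members did. By fry, mesenchymal (adjusted p = 0.00252), autophagy and lysosome (0.00372) and lipid oxidation genes (0.0202) passed upward. The adjusted p values that follow are from camera. The lipid oxidation list, which holds CPT1A, had 3 higher and 3 lower of 14 (adjusted p = 0.881), mesenchymal genes 5 and 1 of 19 (0.0933), autophagy and lysosome genes 6 and 2 of 20 (0.274), S phase and mitosis genes 4 and 7 of 39 (0.467) and NF-kappaB driven genes 4 and 2 of 16 (0.578). In the last list IL8 rose by 1.52 ± 0.20 while the chemokine gene CCL20 fell by 0.30 on the log2 scale. Hypoxia genes had 4 and 5 of 20 (0.508), with EGLN3 higher (1.23 ± 0.20) and LOX lower (-0.48 ± 0.07), and immediate early genes 2 and 3 of 14 (0.857), with DUSP6 lower (-0.54 ± 0.05). Endothelial genes had 3 and 1 of 11 (0.716), microRNA machinery 2 and 2 of 13 (0.881), the BCL2 family 1 and 2 of 12 (0.881), sterol synthesis 1 and 1 of 20 (0.467), blood cell genes 1 and 1 of 4 (0.606) and histones 0 and 1 of 8 (0.944). Median, mean and test differed in sign for the sterol, hypoxia, NF-kappaB, endothelial, immediate early, machinery, BCL2 family, lipid and histone lists. The sign of the median also turned with the scaling for the machinery, NF-kappaB, lipid and blood cell lists.

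**Figure D1:**
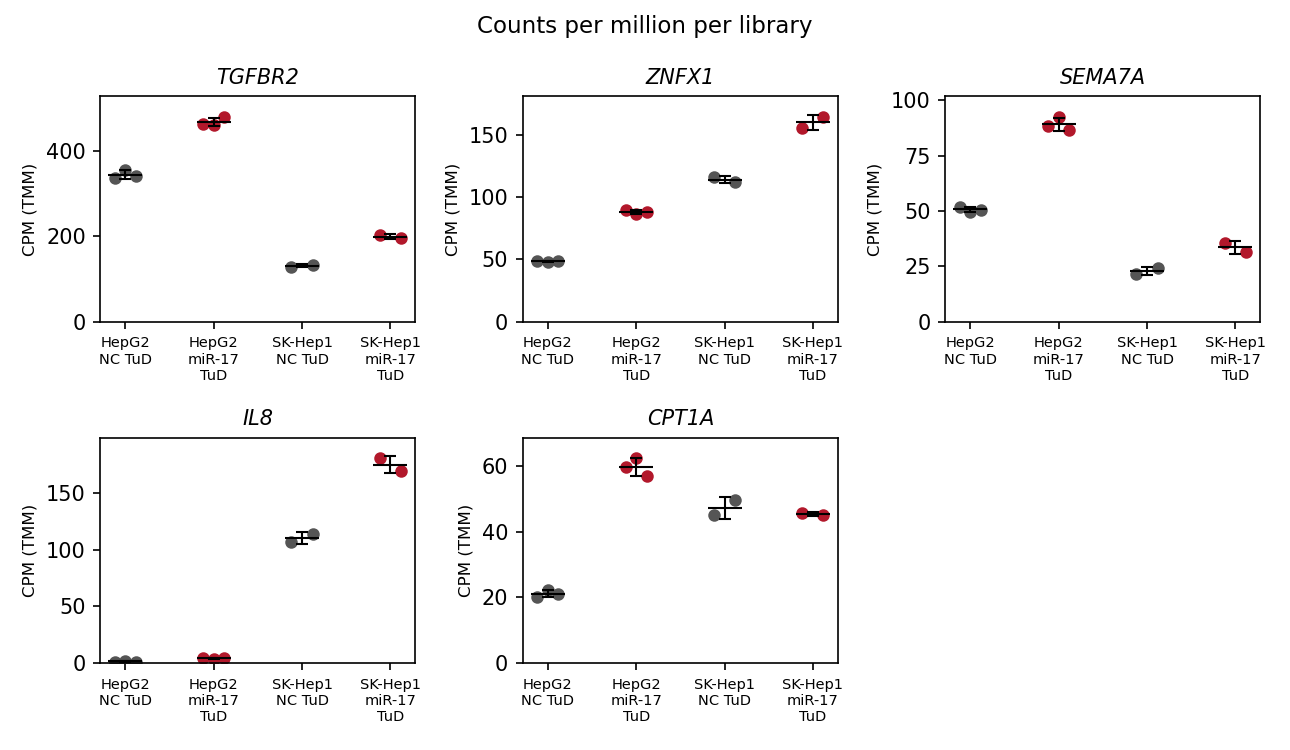
CPM (TMM-scaled, linear axis from 0) of 5 genes in each library, with NC TuD in grey and miR-17 TuD in red, the mean as a bar and the SD as error bars (n = 3 per arm in HepG2, n = 2 in SK-Hep1). TGFBR2, ZNFX1, SEMA7A and IL8 lay higher in miR-17 TuD in both lines, and CPT1A in HepG2 but not in SK-Hep1.

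In SK-Hep1, the same question was put to 2 libraries per arm, and the genes with the smallest adjusted p included IL8 and TGFBR2. IL8 (CXCL8), a neutrophil-attracting chemokine, rose by 0.67 ± 0.06, from 110.3 ± 5.57 to 175.1 ± 7.88 CPM (adjusted p = 9.76e-13). TGFBR2 rose by 0.60 ± 0.05, from 131.3 ± 3.08 to 199.9 ± 5.47 CPM (adjusted p = 1.39e-13). The secreted hormone gene STC1 rose by 0.63 ± 0.08 from 34.6 ± 3.01 to 53.7 ± 2.5 CPM, and SEMA7A, a membrane-anchored semaphorin, by 0.54 ± 0.09. CDK6, a G1 kinase, fell by 0.29 on the log2 scale, and the imprinted gene PEG10 fell by 0.31.

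Of the 13349 genes, 116 were called, 89 higher and 27 lower. Further large increases were in EFR3B (0.81 ± 0.15), CPS1 (0.82 ± 0.15), GPR137B (0.76 ± 0.14) and CXCL2 (0.55 ± 0.13). Further decreases were in ALB and AFP (given with the hepatocyte genes), CELSR2 (-0.67 ± 0.12), the repair gene BRCA2 (-0.38 ± 0.10), BRWD3 (-0.30 ± 0.08) and GINS1 (-0.28 ± 0.06). The number of calls rested on every library: it was 49 without miR-17 TuD replicate 1, 70 without miR-17 TuD replicate 2, 67 without NC TuD replicate 1 and 54 without NC TuD replicate 2. On the deposited log2 matrix it was 136, with 60 higher and 76 lower, and only 49 of the 116 were called there in the same direction. Of 48 named genes called in SK-Hep1, 18 kept the call without each of its libraries in turn, IL8, TGFBR2, STC1, SEMA7A, CDK6, PEG10 and CELSR2 among them. The call was lost without NC TuD replicate 2 for CPS1 and EFR3B, without miR-17 TuD replicate 1 for GPR137B, without either of NC TuD replicate 2 and miR-17 TuD replicate 2 for GINS1, without any of the libraries except miR-17 TuD replicate 2 for CXCL2, and without any 1 library for BRCA2 (-0.46 to -0.31) and BRWD3 (-0.37 to -0.22). On the deposited log2 matrix, a fit added after seeing the data, 24 of the 48 lost the call (adjusted p from 0.0627 to 0.999) with no change of direction. These were STC1 (adjusted p = 0.657), EFR3B, GPR137B, CXCL2, ALB, BRCA2 and BRWD3, and among the list members given below IL1B (adjusted p = 0.767), CXCL1, IRF9, OAS1, OAS2, SQSTM1, F3, ULK1, MKI67, CENPF, BUB1B, LOX, ANGPTL4, FGA, IER3 and DUSP1, together with NUCKS1.

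Targets of the miR-17 family rose in SK-Hep1 as well: 11 of 69 tested members were higher and none lower (21 and 0 when adjusted over the list alone), with a list median of 0.10. The list gave camera adjusted p = 1.78e-18, and adjusted p = 0.00663 with an estimated correlation. After TGFBR2, these included ZNFX1 (0.49 ± 0.05), PLEKHA3 (0.47 ± 0.09), MINK1 (0.45 ± 0.06), RGMB (0.40 ± 0.05), the coagulation gene F3 (0.33 ± 0.07), PKD2 (0.31 ± 0.08), the autophagy kinase gene ULK1 (0.27 ± 0.07), TMEM127 (0.26 ± 0.07) and SQSTM1 (0.21 ± 0.04). Left out in turn, any 1 of the 4 SK-Hep1 libraries ended the call of PKD2 (0.30 to 0.32), ULK1 (0.23 to 0.31) and TMEM127 (0.23 to 0.29), 3 of them that of F3 and SQSTM1, and 2 that of PLEKHA3, while ZNFX1, MINK1 and RGMB kept theirs. CDKN1A was at 0.16 ± 0.04 and missed the threshold (adjusted p = 0.0516). E2F1 was at 0.11 ± 0.07 (adjusted p = 0.729), BCL2L11 at -0.12 ± 0.16, PKD1 at 0.04 ± 0.09, MCM7 at -0.12 ± 0.04 and MYC at -0.05 ± 0.05, none past the test.

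NF-kappaB driven cytokine genes formed the clearest other group in SK-Hep1. Of 16 tested, 7 rose and none fell (12 and 0 when adjusted over the list alone), with a median of 0.27. They included IL8, the chemokine gene CXCL1 (0.31 ± 0.05), the interleukin gene IL1B (0.29 ± 0.05) and ICAM1, an adhesion receptor for leukocytes (0.35 ± 0.06). The list gave adjusted p = 1.09e-24, and adjusted p = 0.00539 with an estimated correlation. Interferon-stimulated genes were higher in 3 of 26 (8 adjusted over the list alone), namely IRF9 (0.38 ± 0.08), OAS1 (0.33 ± 0.08) and OAS2 (0.31 ± 0.07), with adjusted p = 1.01e-14 for the list, and adjusted p = 0.0304 with an estimated correlation. Of 39 S phase and mitosis genes 3 fell and none rose (9 and 1 adjusted over the list alone): the proliferation marker gene MKI67 (-0.17 ± 0.04), CENPF (-0.20 ± 0.05) and BUB1B (-0.22 ± 0.06). The call of MKI67 (-0.19 to -0.15) and BUB1B (-0.24 to -0.21) was lost without any 1 of the 4 libraries, and that of CENPF without NC TuD replicate 2 or miR-17 TuD replicate 1. Their list had a median of -0.10, adjusted p = 5.09e-15, and adjusted p = 0.0346 with an estimated correlation. The hypoxia list had 1 riser of 20, LOX at 0.21 ± 0.05 (2 adjusted over the list alone; adjusted p = 0.000137, and adjusted p = 0.0346 with an estimated correlation). The immediate early list had 2 of 14, IER3 at 0.23 ± 0.05 and DUSP1 at 0.37 ± 0.10, also when adjusted over the list alone (adjusted p = 0.000137, and adjusted p = 0.04 with an estimated correlation).

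Smaller list changes in SK-Hep1 did not hold with an estimated correlation. By fry, the TGF-beta or BMP list (adjusted p = 0.085), the histone list (0.0843) and the hepatocyte list given further on (0.0843) did not pass either. Of 21 TGF-beta or BMP responsive genes 1 rose (4 adjusted over the list alone; adjusted p = 0.00273, and adjusted p = 0.162 with an estimated correlation). Of 20 autophagy and lysosome genes 1 rose, ATG16L1 at 0.39 ± 0.08 (1 adjusted over the list alone; adjusted p = 0.0102, and adjusted p = 0.0644 with an estimated correlation). None of 8 histone genes passed, while the list did (adjusted p = 0.0295, and adjusted p = 0.162 with an estimated correlation). The other lists did not pass: ribosomal protein genes (0 called of 30, adjusted p = 0.925), MYC-bound genes (0 of 30, 0.557), epithelial genes (1 of 16, CLDN1 at 0.37 ± 0.09, 0.431), p53 targets (1 of 20, TNFRSF10B at 0.18 ± 0.05, 0.431), unfolded protein genes (0 of 20, 0.431) and lipid oxidation (1 of 14, ANGPTL4, 0.106). The same held for microRNA machinery (0 of 13, 0.074), the BCL2 family (0 of 12, 0.173), sterol synthesis (0 of 20, 0.301), mesenchymal (0 of 19, 0.497), endothelial (0 of 11, 0.953) and blood cell genes (1 of 4, LYZ, 0.301). Median, mean and test differed in sign for the machinery, lipid, mesenchymal and endothelial lists, and the median turned with the scaling for the endothelial, blood cell and ribosomal lists.

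Among list members named here, the calls of DUSP1 and TNFRSF10B were lost without any 1 of the 4 SK-Hep1 libraries, those of OAS1, OAS2, IER3 and LOX without 3 of them, those of IRF9, ATG16L1, CLDN1 and ANGPTL4 without 2, and those of CXCL1 and ICAM1 without miR-17 TuD replicate 1, while IL1B kept its call without each of them in turn.

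Hepatocyte transcripts, which SK-Hep1 hardly expressed, moved both ways: 6 of 26 fell and 4 rose (10 and 4 adjusted over the list alone), with adjusted p = 0.000275 for the list, and adjusted p = 0.18 with an estimated correlation. ALB had 59 and 113 counts in the NC TuD libraries against 0 and 4 in miR-17 TuD, a ratio of 40.4 (95% interval 15.5 to 150.0), and AFP 62 and 76 against 11 and 7, a ratio of 7.2 (4.39 to 12.5). AHSG had 12 and 38 counts against 0 and 1, a ratio of 47.0 (8.05 to 1890). The 4 that rose were CPS1, the first enzyme of the urea cycle, and the fibrinogen genes FGA, FGB and FGG. FGA had 48 counts in miR-17 TuD and 8 in NC TuD, a ratio of 6.39 (3.0 to 15.6). LYZ, on the list of blood cell genes but abundant in HepG2, fell along with ALB, from 48 counts to 1. Genes on no list that were at least 1000-fold higher in HepG2 were also more abundant in the SK-Hep1 NC TuD libraries, by a ratio of 2.56 (2.17 to 3.04) over 65 genes. The lowest ratio of any pair of libraries was 1.41, and 135 genes on no list that were at least 50-fold higher in HepG2 gave 1.17 (1.12 to 1.23). Without genes at least 50-fold higher in HepG2, a choice made after seeing the data, 89 genes were called in SK-Hep1, 76 higher and 13 lower.

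Changes in 1 direction in both lines were mostly increases. 47 genes rose in both lines where 9.5 were expected from independent calls (odds ratio 9.65, Fisher's exact p = 5.51e-23, two-sided). EFR3B, IL8, SEMA7A (0.81 ± 0.06 in HepG2), the centromere gene CENPQ (0.58 ± 0.08 and 0.53 ± 0.09), TBC1D9 (0.91 ± 0.06 and 0.52 ± 0.09), ZNFX1, RASA2, a negative regulator of RAS (0.48 ± 0.11 and 0.50 ± 0.09), and TGFBR2 had the largest smaller change. 11 genes fell in both, against 2.32 expected (odds ratio 7.38, Fisher's exact p = 6.39e-06). Those named by the rule were AFP, ALB, CDK6, PEG10 and NUCKS1 (-0.16 ± 0.04 and -0.21 ± 0.04). HepG2 material in the SK-Hep1 NC TuD libraries may explain the decreases of AFP and ALB there. Without genes at least 50-fold apart between the lines, 3 genes were lower in both, and Fisher's test was not repeated for them. In HepG2 the call of PEG10 was lost without miR-17 TuD replicate 1 or 2 or NC TuD replicate 2 or 3. In SK-Hep1 the call of RASA2 was lost without NC TuD replicate 1 and that of NUCKS1 without NC TuD replicate 1 or miR-17 TuD replicate 1. A further 11 genes were called in opposite directions. Across all tested genes the fold changes of the lines were hardly related (Pearson 0.023, Spearman 0.099), and across the 8561 genes with log2 CPM above 3 in both lines they were weakly related (0.228 and 0.189). These are relations across genes, which are not independent replicates. Without 1 SK-Hep1 library, the number called in 1 direction in both lines went from 58 to 29 (without miR-17 TuD replicate 1), 31 (without NC TuD replicate 2) or 37 (without NC TuD replicate 1), and it was 42 (39 higher and 3 lower) when genes at least 50-fold apart between the lines were left out before p was adjusted.

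**Figure D2:**
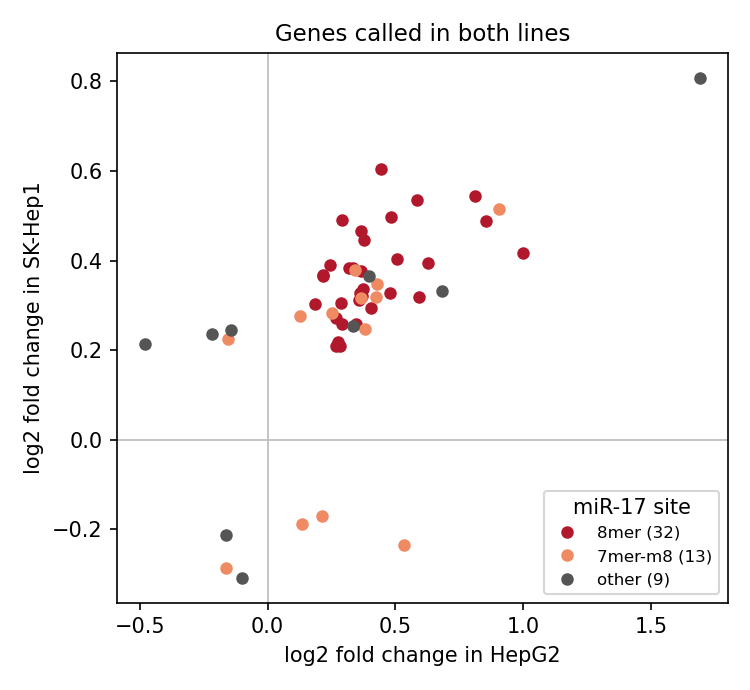
Log2 fold changes (miR-17 TuD over NC TuD) in HepG2 and SK-Hep1 of the 54 genes called in both lines, coloured by miR-17 site, with genes at least 50-fold apart between the lines, IL8 among them, left out after the calls were made on all tested genes. Of these, 44 were higher in both, 32 of them with an 8mer, 3 were lower in both and 7 went in opposite directions.

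Sites for the miR-17 seed were set against the fold changes to ask whether transcripts that the family could bind moved as a set. Among the 47 genes that rose in both lines, 33 (70.2%) had an 8mer in the longest 3′UTR, against 5.33% of tested genes, and 41 (87.2%) had an 8mer or 7mer-m8, against 25%. In TGFBR2 the 8mer lies at nucleotides 30691867 to 30691874 of chromosome 3 (GRCh38), 268 nucleotides into the 3′UTR. ZNFX1 has 2, at 49246776 to 49246783 and 49245936 to 49245943 of chromosome 20, SEMA7A has 1 at 74409328 to 74409335 of chromosome 15, and IL8 has 1 at 73743057 to 73743064 of chromosome 4. Outside the target list, the SK-Hep1 risers IRF9, ATG16L1 and STC1 also have an 8mer, while CXCL1, IL1B, ICAM1, OAS1 and OAS2 have no 8mer. CPT1A and TBC1D9 have a 7mer-m8, and EFR3B, KLF7 and FLRT3 have no site. By class, 24.6% of genes with an 8mer rose in HepG2, 12.5% with a 7mer-m8, 9.32% with a 7mer-A1 and 9.24% with none, and in SK-Hep1 the shares were 5.81%, 0.575%, 0.484% and 0.318%.

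For the set fixed as the main test, 3314 genes with an 8mer or 7mer-m8 lay 0.02 log2 higher than 9108 genes with no site in HepG2 (0.0245, camera p = 0.0258), which did not pass with an estimated correlation (p = 0.145). It also missed the threshold without miR-17 TuD replicate 3 (0.0071), NC TuD replicate 1 (0.0145) or NC TuD replicate 3 (0.0158). In SK-Hep1 the same 3314 genes lay 0.0208 higher than the 9108, which did not pass (camera p = 0.174; exact permutation p = 0.3333 over libraries, the smallest that 2 against 2 can give). In HepG2 the exact permutation p of this set was 0.3, where 0.1 is the smallest possible. Without SK-Hep1 NC TuD replicate 2 the SK-Hep1 shift turned to -0.0038. Of 419 other 7-mers with the same bases, 23 (5.49%) shifted at least as far as the site in HepG2 and 19 (4.53%) in SK-Hep1. With 8mer genes alone, an alternative set in advance, 706 genes were 0.0764 higher in HepG2 (p = 1.29e-06, and p = 0.0242 with an estimated correlation) and 0.0461 higher in SK-Hep1 (p = 6.54e-07, and p = 0.0221 with an estimated correlation). Genes with 1 and with 2 or more 8mers had medians of 0.06 and 0.09 in HepG2 and of 0.03 and 0.09 in SK-Hep1. Taken per library, the 8mer set was 0.0866 higher in miR-17 TuD than in NC TuD in HepG2 (exact permutation p = 0.1, the smallest that 3 against 3 can give) and 0.0593 higher in SK-Hep1 (exact permutation p = 0.3333, the smallest that 2 against 2 can give).

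**Figure D3:**
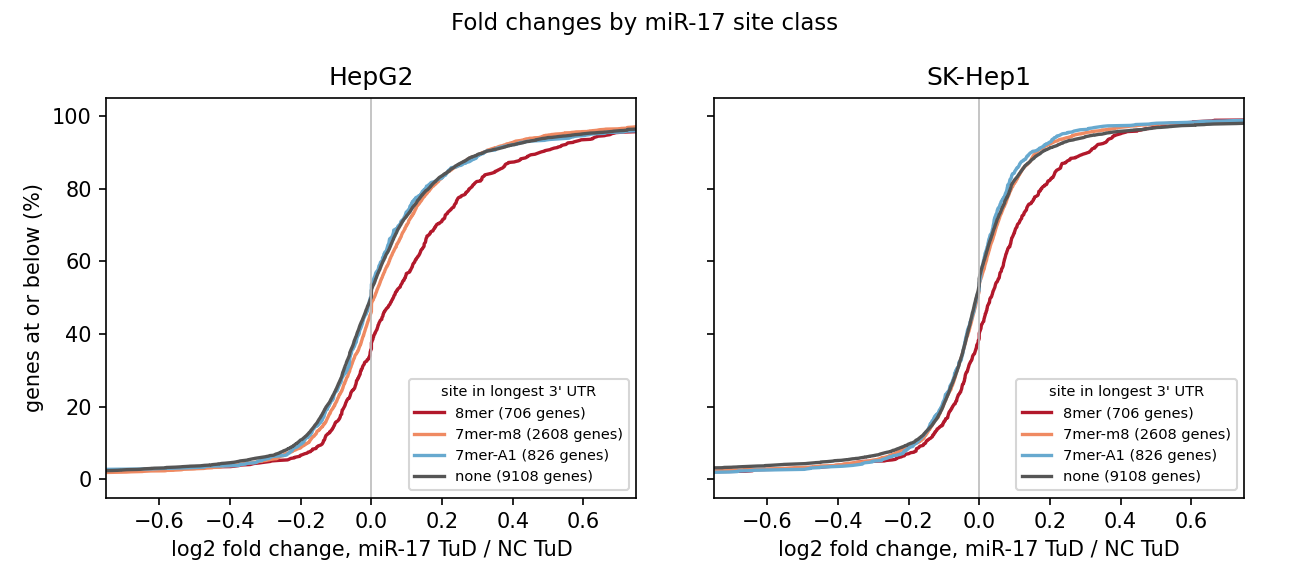
Cumulative share of genes (%) by log2 fold change, miR-17 TuD over NC TuD, for genes with an 8mer, 7mer-m8, 7mer-A1 or no miR-17 site in the longest 3′UTR, with the axis drawn from -0.75 to 0.75. The 8mer curve lies to the right in both lines, with a median of 0.06 in HepG2 and 0.03 in SK-Hep1, and the other curves have medians between -0.01 and 0.01.

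The responses of the lines were compared directly to find genes that the decoy lines changed by different amounts. DKK1, a secreted inhibitor of Wnt signalling, fell in HepG2 (-0.74 ± 0.04) and stood at 0.12 ± 0.04 in SK-Hep1, a difference of 0.86 ± 0.05 (adjusted p = 3.46e-18). CPT1A, which rose in HepG2, stood at -0.06 ± 0.07 in SK-Hep1, a difference of -1.56 ± 0.10 (adjusted p = 5.83e-18). PRKAR1A, a regulatory subunit of protein kinase A, the MAP kinase phosphatase gene DUSP6, LOX, a cross-linker of collagen, STMN3 and the zinc transporter gene SLC39A14 likewise responded higher in SK-Hep1, by 0.54, 0.68, 0.69, 0.66 and 0.43. SDPR, GPR56, KLF7, SYNE2 and CD109 responded lower in SK-Hep1, with differences of -0.86, -1.07, -1.50, -0.77 and -0.70. In all, 500 genes passed, 165 higher and 335 lower in SK-Hep1. By list, ribosomal protein genes differed upward in SK-Hep1 (8 of 30 members, 21 adjusted over the list alone; adjusted p = 9.97e-19, and adjusted p = 0.0798 with an estimated correlation). Targets of the miR-17 family differed downward (5 of 69 members, 8 adjusted over the list alone; adjusted p = 0.000177, and adjusted p = 0.0843 with an estimated correlation), as in ZNFX1 (-0.37 ± 0.07) and FYCO1 (-0.53 ± 0.09). Further lists differed upward in SK-Hep1, each with 1 or more members such as NPM1 (0.21), HSPA5 (0.34), LOX and DUSP6: MYC-bound genes (4 of 30; adjusted p = 3.63e-08), hypoxia (5 of 20; 0.000103), unfolded protein (3 of 20; 0.00107) and immediate early genes (2 of 14; 0.017), at adjusted p = 0.0798, 0.0798, 0.0798 and 0.131 with an estimated correlation. When adjusted over the list alone, 13, 5, 5 and 2 of their members were higher, and 2 immediate early genes were lower. The call of NPM1 was lost without SK-Hep1 NC TuD replicate 2 (0.20). S phase and mitosis (4 of 39; adjusted p = 0.000181), epithelial (2 of 16; 0.000818), mesenchymal (4 of 19; 0.0398) and hepatocyte genes (7 lower and 4 higher of 26; 0.0398) differed downward, as in MKI67 and KRT8, at adjusted p = 0.205, 0.0843, 0.131 and 0.42 with an estimated correlation. Adjusted over the list alone, 10, 3, 4 and 10 of their members were lower, and 1 S phase or mitosis gene and 4 hepatocyte genes were higher. The number of genes fell to 289, 329, 312 and 266 without SK-Hep1 NC TuD replicate 2, NC TuD replicate 1, miR-17 TuD replicate 1 and miR-17 TuD replicate 2, and to 310 without HepG2 NC TuD replicate 1.

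The control decoy lines showed how far the 2 backgrounds lie apart. Hepatocyte genes set HepG2 off: 25 of 26 were lower in SK-Hep1 and 1 higher, the same counts as when adjusted over the list alone (adjusted p = 2.66e-15, and adjusted p = 0.00607 with an estimated correlation). APOB, the main protein of low-density lipoprotein, stood at 22480 CPM in HepG2 and 13.9 in SK-Hep1, ALB at 13570 and 5.78, and AFP at 7480 and 4.67. VIM, the mesenchymal filament vimentin, stood at 1.98 CPM in HepG2 and 8822 in SK-Hep1 (log2 12.12 ± 0.10), although the mesenchymal list as a whole, with 11 of 19 higher and 8 lower, did not pass (adjusted p = 0.121), and FN1 (fibronectin) was lower in SK-Hep1 (-1.37 ± 0.04). NF-kappaB driven genes were higher in SK-Hep1 in 12 of 16, such as IL1B (0.174 and 346.5 CPM) and BIRC3 (4.49 and 247.9 CPM), and interferon-stimulated genes in 22 of 26, such as OAS3 (41.5 and 234.0 CPM) and IFITM3. These lists gave adjusted p = 0.00313 and 0.00013, and adjusted p = 0.372 and 0.382 with an estimated correlation, and the counts were the same when adjusted over the list alone. The endothelial markers ENG and ROBO4 were higher in SK-Hep1 by 4.29 ± 0.11 and 4.42 ± 0.16, while 7 of the 11 tested endothelial genes were lower (adjusted p = 0.884). The abundant keratins KRT8 (0.85 ± 0.04) and KRT18 (1.34 ± 0.04) were higher, and 11 of 16 epithelial genes lower (adjusted p = 0.0685). In all, 11578 of the 13349 genes differed, 5865 higher and 5713 lower in SK-Hep1.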

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

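The adjusted test and the base composition test of the 8mer, both tests of HepG2 material in SK-Hep1 libraries and the HepG2 fits with 2 libraries per arm were chosen after the result was seen, and for the wider site set the tests were planned but their bounds were set after it was seen. The genes below were picked out because the difference between the responses of the 2 lines itself passed the test. They were 59 of the 143 named genes. Values are SK-Hep1 minus HepG2 responses on the log2 scale.

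The response was higher in SK-Hep1 for 23 genes. These were the fibrinogen genes FGA (3.06), FGB (3.06) and FGG (2.77), CPS1 (0.75), the signalling genes DKK1 (0.86), PRKAR1A (0.54), DUSP6 (0.68) and TLE4 (1.08), and the hypoxia and matrix genes LOX (0.69), P4HA1 (0.41), SLC2A1 (0.25), BNIP3 (0.34) and CTGF (0.35). The growth genes RPL11 (0.23), RPL5 (0.19), RPS6 (0.18), NPM1 (0.21) and GNL3 (0.23) followed, with HSPA5 (0.34), IER3 (0.38), ICAM1 (0.40), STMN3 (0.66) and SLC39A14 (0.43). The fibrinogen values are uncertain, since SK-Hep1 NC TuD and miR-17 TuD had 8 and 48 counts of FGA, 4 and 21 of FGB and 5 and 24 of FGG. The FGA difference ran from 2.32 to 4.88 over the libraries left out.

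The response was lower in SK-Hep1 for 36 genes. Transcripts abundant in HepG2 were AHSG (-5.11), LYZ (-5.00), ALB (-4.74) and AFP (-2.30). Over the libraries left out they ran from -7.43 to -4.10, -7.34 to -4.11, -8.83 to -3.82 and -2.70 to -1.97. AHSG and LYZ had 1 count each in SK-Hep1 miR-17 TuD, so their fitted values are uncertain, with ratios of NC TuD to miR-17 TuD counts of 47.0 (8.05 to 1890) and 45.1 (7.71 to 1820). HERC5 (-2.75), SLFN5 (-2.22), CPT1A (-1.56), IGFBP7 (-1.54), KLF7 (-1.50), FLRT3 (-1.32), GPR56 (-1.07), SDPR (-0.86), IL8 (-0.86), SYNE2 (-0.77) and CD109 (-0.70) came next. Mesenchymal, endothelial and matrix genes were COL1A1 (-0.69), ENG (-0.62), TAGLN (-0.42), ACTA2 (-0.40), CDH2 (-0.36) and TGM2 (-0.28), with the epithelial KRT8 (-0.25). Targets and p53 genes were FYCO1 (-0.53), ZNFX1 (-0.37), CDKN1A (-0.24), FAS (-0.42), FDXR (-0.35) and DDB2 (-0.35). CELSR2 (-0.58), BIRC3 (-0.57), CCNE2 (-0.52), BRCA2 (-0.43), AGO2 (-0.41), TBC1D9 (-0.39), MKI67 (-0.38) and PEG10 (-0.21) complete them.

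Of the 59 differences, 34 kept the call without each of the 10 libraries in turn and 25 lost it without at least 1, with no change of direction. Any 1 of the 4 SK-Hep1 libraries, left out, ended the call of RPS6 (0.16 to 0.21 over all libraries left out), RPL5 (0.17 to 0.21), IGFBP7 (-1.79 to -1.27), ACTA2 (-0.42 to -0.37) and TBC1D9 (-0.43 to -0.36). IGFBP7 had adjusted p = 0.324 without NC TuD replicate 1. Any of 3 SK-Hep1 libraries did so for BRCA2 (-0.51 to -0.35), TAGLN (-0.58 to -0.28), FAS (-0.49 to -0.34), GNL3 (0.19 to 0.27) and PEG10 (-0.25 to -0.16), and either of 2 for ENG (-0.75 to -0.50), AGO2 (-0.47 to -0.35), CCNE2 (-0.63 to -0.40), BNIP3 (0.23 to 0.46), FLRT3 (-1.48 to -1.19) and SLC2A1 (0.22 to 0.28). A single SK-Hep1 library did so for CPS1 (0.51), NPM1 (0.20) and DDB2 (-0.34) with NC TuD replicate 2 left out, FDXR (-0.33) with NC TuD replicate 1, and CDKN1A (-0.23), CELSR2 (-0.52) and RPL11 (0.19) with miR-17 TuD replicate 2. HepG2 NC TuD replicate 1, left out, ended the call of IL8 (-0.80) and BIRC3 (-0.48), and also of RPS6, RPL5, IGFBP7, ACTA2, BRCA2, ENG, FAS, GNL3, PEG10, AGO2 and CCNE2. Leaving out HepG2 miR-17 TuD replicate 1 ended that of BIRC3, DDB2, RPS6, RPL5, IGFBP7, ENG and TAGLN, miR-17 TuD replicate 2 that of RPS6 and RPL5, miR-17 TuD replicate 3 that of BIRC3 and BRCA2, NC TuD replicate 2 that of RPS6, ENG and TAGLN, and NC TuD replicate 3 that of TBC1D9. DESeq2, limma-voom or the replicate block ended it for some of the 25 and for none of the other 34.

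HepG2 had many more called genes than SK-Hep1, 2571 against 116 in the fit of all libraries. Fitted on its own libraries alone, HepG2 gave 2329 and SK-Hep1 274, so the size of the gap depends on the shared fit. With 2 libraries per arm HepG2 still gave at least 1278 over the 9 choices, which argues against fewer replicates as the whole cause. Variation between SK-Hep1 replicates was no greater, at a biological coefficient of variation of 2.23% against 3.65% in HepG2. What stays open is a difference between the cell lines in their response, and differences that arose when each stable line was derived, which these libraries do not separate. For the 2571 calls in HepG2, the 10 splits of its 6 libraries are too few for a share under 0.05: the real split gave the most (1 of the 10), and the highest other gave 0. Each other split had libraries of both arms on each side, so a difference between arms counted there as variation within a side. The 0 therefore cannot show how many calls would arise without such a difference.

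Genes with a miR-17 site lay slightly higher in miR-17 TuD cells, by 0.0245 in HepG2, where the call was lost with an estimated correlation, and by 0.0208 in SK-Hep1, where it did not pass. The shifts were then adjusted for 3′UTR length, GC content and expression. The smaller of the 2 was 2.69 standard errors from 0, and 2.45 for the 8mer alone. These standard errors treat genes as independent, so they cannot decide whether those properties are the whole cause. The adjusted shifts were no smaller than the unadjusted ones, at 0.0331 in HepG2 and 0.0319 in SK-Hep1, and at 0.0872 and 0.0538 for the 8mer. Base composition stays open for the wider set, since up to 5.49% of 7-mers with the same bases shifted as far. For the 8mer up to 1.09% of 8-mers with the same bases did. Release of targets by the decoy and a difference between the stable lines that follows the site both stay open, and no test here separates them.

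HepG2-specific transcripts such as ALB were lower in the SK-Hep1 miR-17 TuD libraries. For 65 such genes on no list, SK-Hep1 NC TuD libraries held 2.56 times (2.17 to 3.04) the counts of miR-17 TuD libraries, with 1.41 as the lowest ratio of any pair and 1.17 (1.12 to 1.23) over 135 genes at least 50-fold higher in HepG2, so HepG2 material in the NC TuD libraries may explain these decreases, and a change in SK-Hep1 cells stays open. Shares of the HepG2 level were 0.0487% and 0.101% in NC TuD against 0.0346% and 0.0247% in miR-17 TuD, and SK-Hep1-specific genes stood at 0.0252% to 0.0467% in the HepG2 libraries. HepG2 material as the source of the transcripts that rose too is argued against by the other transcripts it would bring: FGA, FGB, FGG, HGD and ALDH1A1, all 5 chosen because they rose, stood at 0.291% of their HepG2 level in miR-17 TuD, while all 81 HepG2-specific genes stood at 0.0195%. The 81 were chosen as at least 1000-fold higher in HepG2, which can hold their share down. The 135 genes at least 50-fold higher stood at 0.284% and 0.271% in miR-17 TuD. Such material would still bring all abundant HepG2 transcripts. ALB had 0 and 4 counts in SK-Hep1 miR-17 TuD, against 128870 or more in each HepG2 library. The cause of the rise in FGA, FGB, FGG, HGD and ALDH1A1 was not tested.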

How the results depend on the processing

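Chosen after the results were seen were the fits on the deposited log2 matrix, those without genes 50-fold apart between lines, those with 2 HepG2 libraries per arm and the crossed block. The target list passed in both lines in each alternative run. Its median was 0.18 to 0.24 in HepG2 and 0.09 to 0.10 in SK-Hep1 over the libraries left out. The 2571 HepG2 calls ranged from 1793 (without NC TuD replicate 1) to 2694 (without miR-17 TuD replicate 3) over single libraries left out. With 2 libraries per arm they ranged from 1278 to 2834, and 2 further choices moved beyond 1.5 times (1466 and 1573). Fewer samples may lower the numbers and do not account for the rise. With equal numbers of libraries the calls still varied with the ones left out, and the cause was not tested. DESeq2 gave 1714 in HepG2 and 86 in SK-Hep1, limma-voom 2515 and 107, RLE scaling 2555 and 134, and no filter 2576 and 150.

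The 116 SK-Hep1 calls were 58 with a replicate block, 62 with crossed numbers in the block and 274 with only the libraries of that line. The replicate block also gave 227 of 500 for the difference of responses and 31 of 58 for both lines. In HepG2 replicate numbers did not pair the arms by their residuals, with correlations from -0.417 to 0.073 for the same number. There miR-17 TuD replicate 2 went with NC TuD replicate 3 (0.366) and miR-17 TuD replicate 3 with NC TuD replicate 2 (0.464). A crossed block was not run for HepG2. In SK-Hep1 the residuals of 2 libraries per arm mirror each other, so the correlation of -0.114 cannot test pairing. The block costs degrees of freedom. Leaving out 1 library gave 49 (SK-Hep1 miR-17 TuD replicate 1) to 171 (HepG2 miR-17 TuD replicate 3) calls in SK-Hep1, with 54, 67 and 70 without NC TuD replicate 2, NC TuD replicate 1 and miR-17 TuD replicate 2. The difference of responses ranged from 266 (without SK-Hep1 miR-17 TuD replicate 2) to 613 (without HepG2 miR-17 TuD replicate 3), and both lines from 29 (without SK-Hep1 miR-17 TuD replicate 1) to 80 (without HepG2 miR-17 TuD replicate 3). An SK-Hep1 arm left with 1 library is assumed to vary like the other groups. Where fewer samples do not account for a change, the cause was not tested.

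The site shift in HepG2 (0.0245) lost its call with 7mer-A1 genes added (0.0211) and with an estimated correlation (0.0245, p = 0.145). It ranged from 0.0071 (without miR-17 TuD replicate 3) to 0.0394 (without miR-17 TuD replicate 2). In SK-Hep1 it passed by camera for the 8mer only (0.0461). The wider set there ranged from -0.0038 (without NC TuD replicate 2, reversed) to 0.0298 (without miR-17 TuD replicate 1). Adjustment for 3′UTR length, GC and expression gave 0.0319 ± 0.0118 (SE), which passed in a regression that treats genes as independent. That regression gave 0.0208 ± 0.0105 without the adjustment, so its result cannot be set against the camera tests of the other settings. Of the 19 list results past the test in HepG2 and SK-Hep1, 8 passed with an estimated correlation. By fry 19 passed too, though not all for the same lists. Of 4672 values for 239 named results, 4295 kept direction and call, 361 lost the call, 12 gained it and 4 reversed, none of them called. The reversed values, over libraries left out, were E2F1 in HepG2 (-0.0174 and -0.0105 to 0.077) and PKD1 in SK-Hep1 (-0.0099 and -0.007 to 0.0957). Of the 48 named genes called in SK-Hep1, 30 lost the call without at least 1 of its libraries and 9 whichever of them was left out. On the deposited log2 matrix, 20 of 110 named calls in HepG2 were lost, among them STRA6, COL26A1, ADAMTS2, SLC17A2, CCL20, ALB, AFP, FGA and PEG10, and 24 of 48 in SK-Hep1, STC1, IL1B, CXCL1, CXCL2, OAS2, EFR3B, ALB and FGA among them. That fit used no weights by count and pooled the variance of each gene over both lines. ALB in HepG2 stood at -0.5164 there and at -0.5145 in the main fit, and STC1 in SK-Hep1 at 0.64 there. When only the libraries of that line were fitted, 111 named results in HepG2 kept direction and call and 1 lost the call. In SK-Hep1, 52 kept both and 2 gained the call. BRWD3 and BUB1B in SK-Hep1 lost the call in 13 settings each, and CDKN1A in SK-Hep1 passed in 11. The cause was not tested. Depth limits genes near 0.199 to 0.233 CPM, the level that 3 counts give.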

Other observations

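Control seeds were set beside the 7-base site of miR-17, each as genes with the site against all searched genes without it. On this measure the miR-17 shift was 0.024 in HepG2 and 0.0201 in SK-Hep1. The main test, against genes with no miR-17 site of any kind, had 0.0245 and 0.0208. Genes with a site for miR-19, made from the same cluster as miR-17, were 0.0249 higher in HepG2, as high as for miR-17, and at -0.002 in SK-Hep1. Without genes that also had a miR-17 site, the miR-19 values were 0.0115 and -0.0059. Those for miR-18 were at -0.012 and -0.0015 (-0.0123 and 5e-04 without miR-17 site genes), for miR-92/25 at -6e-04 and -0.0291 (-0.0043 and -0.0252), and for let-7 at 0.0123 and -0.0086 (0.0084 and 0.0054). For miR-122 they were at 0.0192 and -0.0296 (0.0418 and -0.0272), for miR-21 at -0.0394 and -0.0141 (-0.0517 and -0.0167), for miR-16 at 0.0095 and -0.0104 (0.0301 and -0.0015), and for the miR-302 family, whose seed overlaps that of miR-17, at 0.0113 and 0.0115 (0.0132 and 0.0018). In HepG2 the miR-122 and miR-16 values without miR-17 site genes were above the miR-17 shift.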
